A study of Homo sapiens with 4 samples.

How the data were processed

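Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of RNA polymerase II (Pol II) was analysed in U2OS, a human osteosarcoma cell line. Per the labels' protocols, the cells were transfected with a control siRNA or with an siRNA against NKAP for 48 h and were fixed with 1% formaldehyde for 10 min. The chromatin was sheared by sonication, and the libraries were sequenced as paired reads. The labels list 4 samples: 1 Pol II ChIP library and 1 input library (sheared chromatin without antibody) for each siRNA. The peak lists of the 2 ChIP libraries were analysed, and no file of the input libraries was used here. Each group held 1 ChIP library, so no difference had a replicate check and no test between the conditions was made.

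Per the submitters' processing notes, the tools were bcl2fastq 2.17, Trimmomatic 0.33, Bowtie 1.1.2 and MACS2 2.1.0, and the genome build was hg38. Their settings are not given in the sources used here. Each deposited list held the peaks of 1 library, so the authors called peaks per sample and not on pooled libraries. For each peak the deposited columns gave its position, a score, the fold enrichment of its summit over the background, the −log10 of its p-value, the −log10 of its q-value and the place of its summit. The deposited score was 10 times the −log10 q-value, without its decimals. The fold, p-values and q-values are the authors' own values from their peak caller, and were used here only to describe, rank or filter peaks within a list. The lists ended at −log10 q-values of 3.01 (control) and 3.02 (knockdown), so weaker regions were left out by the authors' threshold. A region with no peak in a list can therefore hold Pol II below that threshold.

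The depth of the libraries was recovered from the lists. The caller writes a fold as (pileup + 1)/(background + 1) and takes p from a Poisson distribution of the pileup, so both values together give the reads and the background at each summit. Whole reads, within 0.01 of a read, came out for 99.9% of the control peaks and 99.99% of the knockdown peaks. Depths were estimated from the caller's background, with the smallest peak width of each list taken as its fragment length. By this estimate the knockdown ChIP library had 0.857 times the depth of the control ChIP library. The depth at which its peaks were called was 0.793 times that of the control. The backgrounds moved in steps of whole reads of a second library of 1.00 and 0.793 times the control ChIP depth, but the sources used here do not state which library served as background. The median peak had 18 reads at its summit in the control list and 19 in the knockdown list, and the lowest had 8 in each.

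Peaks on chromosomes 1 to 22 and X were used. The other sequences held 2218 control peaks (5.75%) and 1526 knockdown peaks (5.47%). Peaks of the lists were called overlapping when they shared at least 1 bp. As a background, each list was moved along its chromosomes by a random distance 100 times. Shares are given with their 95% Wilson interval over peaks or genes. These intervals cover counting error only, and neither neighbouring peaks nor genes are independent.

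Genes came from the RefSeq gene table of the same build, which gives the start and end of 19974 protein-coding genes on these chromosomes. That table holds no strand, exons or transcripts, and no genome sequence was used here. The promoter, 3′ end, exon and intron classes planned before the data were examined were therefore replaced. A gene end was the 1000 bp on either side of the lower or the higher end of a protein-coding gene, so that it took in the promoter and the termination site alike. A flank reached up to 5000 bp outside a gene end. The gene interior was the rest of a protein-coding gene, followed by other annotated genes and by intergenic sequence. Each summit was placed in the first class that held it, in the order gene end, flank, interior, other gene, intergenic. A gene had a gene-end peak when a peak touched either of its end windows. Interiors and flanks were counted in genes of at least 5000 bp with a gene-end peak in both lists, leaving out windows that touched an end of another protein-coding gene; there a summit had to lie in the window. Exon number, CpG content and GC skew were not analysed here.

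The 28 gene lists were fixed before the data were examined, and all 712 entries matched the gene table, by symbol or by an older symbol (CIR1 is CIRSR there). Of the 28 lists, 25 were of protein-coding genes. For each of these with at least 5 carriers of a control gene-end peak, the share also found in the knockdown list was set among 10000 random lists matched on strength (10 groups of the control peak's −log10 p). Its percentile describes these 2 libraries and is not a test of the conditions. The reverse was done from the knockdown list. Named genes followed a rule fixed at the same time: NKAP, the 10 genes of highest fold with a gene-end peak in the control list only, the same for the knockdown list only, the 5 of highest fold in each list, and up to 2 members of each list in both, in control only and in knockdown only. This rule gave 98 genes, and genes on the same peak as a higher-ranked one were skipped. Genes named by other routes are marked as chosen after their values were seen. The results of some genes are not reported here.

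Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The steps were tested on simulated data. A list made to hold 59.8% of the 36345 control peaks gave an overlap of 59.8%. Of 7921 simulated summits, 99.99% had their reads recovered exactly. Among 200 unchanged gene lists, 3% fell outside the central 95% of random lists. Of 200 lists with a retention of 70% against 92%, 80.5% fell below it. Smaller falls and lists of other sizes were not simulated. Alternatives planned before the data were examined were stricter q-values, equal numbers of strongest peaks, the strongest 10000 peaks, all sequences, other overlap rules, and other windows. Control summits were also thinned to 0.842 of their reads and then multiplied by 0.926, the factor by which the caller had scaled the knockdown library to its calling depth. This thinning, a stricter gene-end rule and interior coverage with equal numbers of peaks were added after the data were seen.

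Summit reads and the covered interior of the gene lists were also chosen after the data were seen. Reads at knockdown summits were divided by 0.842, the share of reads that the lists' depths and fragment lengths gave. The fragment lengths were not measured: the smallest peak width of each list, 229 and 225 bp, was taken in their place. Summits had to lie at the same gene end in both lists, and genes with a summit of unrecovered reads were left out. This rule replaced a first one, by which the peak of most reads at either end was taken in each list on its own, after the first values of the gene lists had been seen. Covered interiors ran from 1000 bp inside one end of a gene to 1000 bp inside the other, in genes of at least 5000 bp. Unlike the gene counts, they needed no gene-end peak and took in the ends and flanks of other genes that lay there. Percentiles were computed for 21 gene lists with summit reads, for 19 with covered interiors and for 18 of these with equal numbers of peaks.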

Results

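The study asked how Pol II is distributed over the genome when NKAP is depleted. NKAP is a nuclear protein known to bind RNA, to take part in splicing and to act as a corepressor with HDAC3 in Notch signalling. U2OS cells received a control siRNA or an siRNA against NKAP, and Pol II was profiled in 1 ChIP library of each. All comparisons are between these 2 libraries and have no replicate check. The knockdown library had an estimated 0.857 times the depth of the control library.

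NKAP itself, on chromosome X from 119920672 to 119943751 (hg38), carried a gene-end peak in both lists, 255 bp from its higher-coordinate end. The peak had a fold enrichment of 6.07 and a −log10 p of 9.51 in the control list, and 6.90 and 10.8 in the knockdown list. An siRNA acts on the transcript, so Pol II at the gene does not check the knockdown, and the lists hold no measure of the NKAP transcript.

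The 2 lists had the strongest Pol II sites in common and parted at the weak ones. The control list held 36345 peaks over 38.6 Mb and the knockdown list 26387 peaks over 23.9 Mb. A knockdown peak overlapped 54.2% of control peaks (95% interval 53.7 to 54.7), and a control peak overlapped 82.8% of knockdown peaks (82.4 to 83.3). Lists moved to random places overlapped by 2.04% ± 0.143 and 2.78% ± 0.196 (SD, n = 100 moves). Among protein-coding genes with a gene-end peak, the highest folds of the control list lay at H2AC18 and H2AC19 (96.1 and 91.7), 2 replication-dependent histone genes of chromosome 1, at CCN1 (90.0), a matricellular gene of the immediate early class whose peak also reached DDAH1, at MAT2A (79.1), which encodes the enzyme that makes S-adenosylmethionine, and at TEX2 (77.8). The histone summits lay 1242 and 1201 bp from an end of these genes, on wide peaks shared with H3C14, H4C14, H4C15 and H3C15, and the summit of TEX2 lay 1127 bp from its end. In the knockdown list these lay at EEF1A1 (77.9), the translation elongation factor gene, H3-3B (72.9), a replication-independent histone gene, RPS12 (70.6), MAT2A (63.5) and SRSF7 (63.4), a splicing factor gene. Each of these 9 genes carried a peak in both lists.

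The overlap rose with peak strength. With each list split into 10 groups of equal size, 17.3% (16.1 to 18.6) of the weakest control group were overlapped and 99.9% (99.8 to 99.97) of the strongest. For the knockdown list the weakest group had 60.1% (58.2 to 61.9) and the strongest 99.9% (99.7 to 99.96). The 16644 peaks of the control list alone had a median fold of 5.52 and a median width of 391 bp, against 10.0 and 1236 bp for the 19701 overlapped control peaks. The 4526 peaks of the knockdown list alone had a median fold of 5.92 and a median width of 332 bp. When the lists were brought to equal numbers of strongest peaks, the overlap was 67.6% of control peaks and 76.9% of knockdown peaks.

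**Figure D1:**
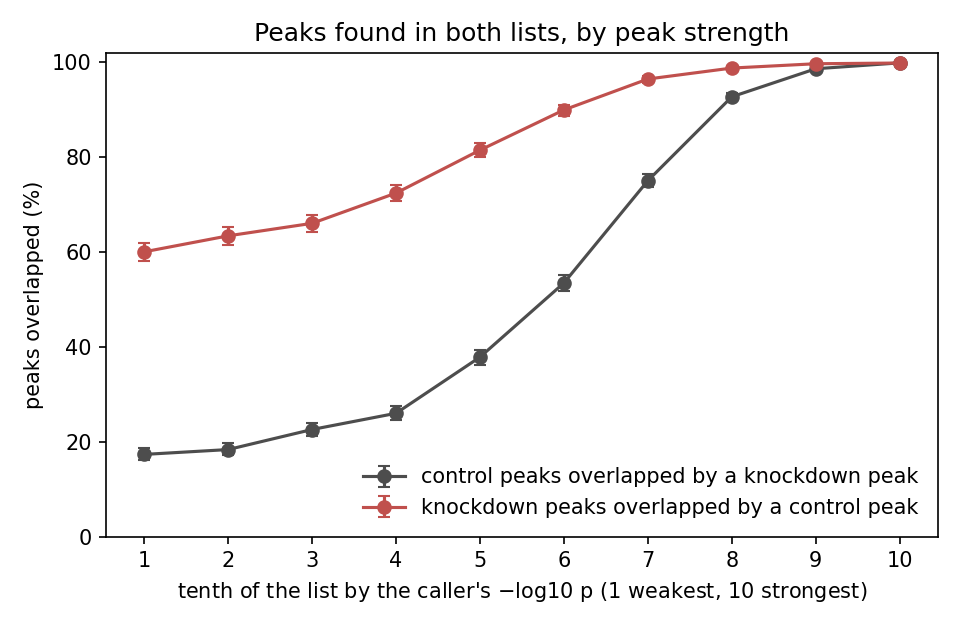
Share of the peaks of each list that were overlapped by a peak of the other list (y axis, percent), in 10 groups of equal size ordered by the caller's −log10 p (x axis, 1 weakest to 10 strongest); points are shares and bars 95% Wilson intervals over peaks. The control list runs from 17.3% to 99.9% and the knockdown list from 60.1% to 99.9%.

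The ends of protein-coding genes held a larger share of the knockdown peaks, and gene interiors and flanks a smaller one. Gene ends took 33.7% of control summits (33.2 to 34.2) and 41.8% of knockdown summits (41.2 to 42.4), a difference of 8.12 percentage points (7.35 to 8.89). Gene interiors took 30.6% (30.2 to 31.1) and 25.2% (24.7 to 25.7), and flanks 13.4% (13 to 13.7) and 10.7% (10.3 to 11). Intergenic sequence took 14.6% of control and 14.7% of knockdown summits, and other annotated genes 7.67% and 7.69%. Randomly moved knockdown summits fell at gene ends in 3.04% of cases and in interiors in 41.4%.

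Peaks at gene ends were the most often found in both lists. Of the control summits at gene ends 79.8% (79.1 to 80.5) belonged to peaks overlapped by a knockdown peak, against 38.3% (37.4 to 39.2) in interiors, 34.3% (33.0 to 35.7) in flanks, and 49.2% in other genes and in intergenic sequence alike. With gene ends weighted to the strength of the interior peaks, the gene-end share stayed 15.3 percentage points higher, and it was higher in 10 of 10 strength groups. The share of knockdown peaks found in the control list was likewise 11.4 percentage points higher at gene ends than in interiors at matched strength, in 9 of 10 groups. The rise in the gene-end share depended on list length. It was 1.47 percentage points (0.627 to 2.31) with equal numbers of strongest peaks, and the strongest 10000 peaks of each list gave −1.15 (−2.47 to 0.171).

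**Figure D2:**
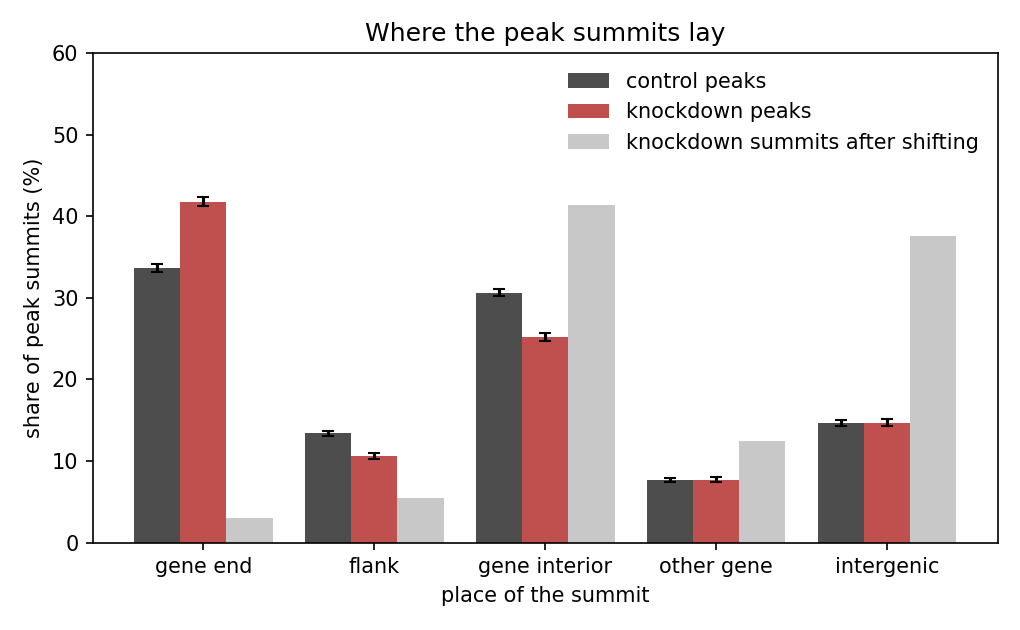
Share of peak summits (y axis, percent) at gene ends, in flanks, in gene interiors, in other annotated genes and in intergenic sequence (x axis) for the control list, the knockdown list and knockdown peaks moved to random places; error bars on the first 2 are 95% Wilson intervals over peaks. Gene ends hold 33.7% of control and 41.8% of knockdown summits, against 3.04% after moving.

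Most genes with a Pol II peak at an end had one in both libraries, and this held for the housekeeping and growth gene groups. The peaks of a gene did not have to lie at the same end in both lists. Of 19974 protein-coding genes, 10986 had a gene-end peak in both lists, 970 in the control list only, 291 in the knockdown list only and 7727 in neither. The knockdown list thus kept 91.9% (91.4 to 92.4) of the control genes, and the control list held 97.4% (97.1 to 97.7) of the knockdown genes. All carriers were kept for the cytosolic ribosomal proteins (51 of 51, among them RPL3 with control and knockdown folds of 72.1 and 56.3), spliceosome and splicing factors (33 of 33, among them SRSF2), Pol II subunits and elongation factors (31 of 31, among them POLR2A and HEXIM1, the inhibitor of the elongation kinase P-TEFb), and mitosis and G2/M genes (30 of 30, among them CDC20 and CDC25C). All were also kept for R-loop prevention and removal (27 of 27, among them the RNA helicase gene DDX5), where R-loops are RNA:DNA hybrids formed behind Pol II, and for the replication-dependent histones (24 of 24).

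The same was true of nuclear-encoded oxidative phosphorylation (31 of 31), immediate early genes (27 of 27, among them JUND), the proteasome (24 of 24), the unfolded protein and ATF4 response (22 of 22, among them ATF4 and CALR), glycolysis (19 of 19, among them GAPDH and TPI1), cholesterol synthesis (18 of 18, among them HMGCS1) and the Notch pathway and targets (9 of 9, among them HES1, the Notch target repressor, and JAG1, a Notch ligand). With windows of 2000 bp the Notch genes kept 9 of 10. Random lists of like strength kept a median of 88.9% to 100% beside these 13 lists. Oxidative phosphorylation stood at percentile 97.3 among them and the other 12 between 52.7 and 92.5. A single gene was lost in each of 7 further groups, cell type markers aside. Random lists of like strength kept a median of 88.9% to 97.0% beside these 7, which stood between percentiles 34.6 and 83.6. The losses were thus about those of random lists. CIRSR (CIR1), a corepressor that binds the Notch effector RBPJ, was lost from the 12 carriers among NKAP and its corepressor partners, whose other members with peaks included SIRT1 and NCOR1. CHORDC1, a cochaperone gene, was lost from the 18 heat shock genes, TNFAIP2 from the 18 NF-kB targets and AEN, an apoptosis nuclease, from the 24 p53 targets, though AEN had a peak in both lists with windows of 2000 bp. POLA1, the catalytic subunit of DNA polymerase alpha, was lost from the 33 DNA replication genes, MDC1, a mediator of the DNA damage checkpoint, from the 26 genes of double-strand break repair, and TAGLN, an actin-binding gene of smooth muscle and fibroblasts, from the 16 extracellular matrix and osteoblast genes. With equal numbers of strongest peaks POLA1 had no gene-end peak in either list. The control peak of CIRSR also touched an end of SCRN3. The control folds of these 7 genes ran from 5.60 (POLA1) to 8.60 (CIRSR), against a median of 10.0 for overlapped control peaks. Lost here means that no knockdown peak above the authors' threshold reached the window.

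Among the lists with at least 5 knockdown carriers, interferon-stimulated and Notch genes had the lowest shares of knockdown peaks also found in the control list. Of 12 interferon-stimulated genes with a knockdown peak, 9 had a control peak, with IFI44, IFIH1 and IFIT5 in the knockdown list only, and IFI6 and IFIT2 were in the control list only. IFIT5 was named after its values were seen. The summit of the IFI44 peak lay in the flank, 1014 bp from the gene's higher-coordinate end, so that only part of the peak reached the window. IFIH1, which encodes the RNA sensor MDA5, had a knockdown fold of 5.55, with the nearest control peak 21685 bp away. Of 11 Notch genes with a knockdown peak 9 had a control peak. DTX1, a Notch target and regulator (fold 3.95), and NOTCH3, a Notch receptor gene (fold 5.92), were in the knockdown list only. The interferon and Notch groups stood at percentiles 2.00 and 2.04 of random lists of like strength. They were the 2 of 43 percentiles computed that lay outside the central 95%, about as many as chance gives. With equal numbers of strongest peaks they stood at 8.96 and 6.13, and neither IFI6 nor IFIT2 had a peak. With windows of 2000 bp they stood at 2.23 and 0.27, and among random lists matched on fold at 1.50 and 3.53. CCL2, a chemokine gene, and PSMA1, of the proteasome, were also in the knockdown list only. The PSMA1 peak also touched an end of PDE3B, and the nearest control peak lay 3256 bp from an end of PSMA1. The IFIH1 peak also touched an end of GCA.

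Genes of other cell types had few peaks. Control and knockdown carriers were 3 and 2 of 21 hepatocyte markers, 5 and 4 of 19 neuron markers, 3 and 3 of 20 lymphocyte markers, and 3 and 2 of 20 keratinocyte markers. Each of these 4 lists had 1 gene in the control list only, and the lymphocyte markers also had 1 in the knockdown list only. The peak of TF, which encodes transferrin, lay at an end shared with TOPBP1. Among noncoding genes, the small nuclear RNA genes transcribed by Pol II had a peak at 16 of 17 in the control list and 15 in the knockdown list, with RNU5D-1 in the control list only. Long noncoding RNA and snoRNA host genes had a peak at 21 of 22 in each list, among them MALAT1, NEAT1 and GAS5, and H19 had none. Genes transcribed by Pol III had a peak at 11 of 18 in the control list and 12 in the knockdown list, the difference being VTRNA1-2. These noncoding genes were named after their values were seen. For them any peak within 1000 bp of either end was counted, and other genes on that peak were not checked. A peak counted at a gene transcribed by Pol III may therefore belong to a neighbour.

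Most of the genes of highest fold found in a single list had a peak of the other list just outside the window, which was not so for single-list genes as a whole. Of these, 29.7% of the 970 in the control list only and 30.9% of the 291 in the knockdown list only had a peak of the other list within 5000 bp. The 10 genes of highest fold in the control list only included TOB1 (fold 39.9), SIAH1, FUT6, NADK, BTBD18, TRPV2, SLFN13, ANAPC5 and S1PR4 (fold 21.9). In each of these 9 a knockdown peak lay between 1004 and 1236 bp from a gene end, just outside the window. Of the 10 for the knockdown list, CYREN (fold 16.2), RHBDF1, TSGA10IP, CACNG8, C6orf58, CRYM and NKX6-1 likewise had a control peak 1014 to 1304 bp away. The other 3 had none within 5000 bp. They were SLC6A17, a neuronal amino acid transporter gene (chromosome 1, 110150494 to 110202202, fold 14.2), G0S2, an inhibitor of triglyceride breakdown (chromosome 1, 209675412 to 209676390, fold 11.1), and TUBB2B, a beta-tubulin gene (chromosome 6, 3224277 to 3227653, fold 10.8). Their summits lay 198, 74 and 43 bp from a gene end, and the nearest control peak 7865, 17458 and 19674 bp away.

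A stricter rule, chosen after the data were seen, asked for a summit within 1000 bp of a gene end and no peak of the other list within 5000 bp of either end. It left 647 genes in the control list only and 190 in the knockdown list only. Among the highest control folds, also named after their values were seen, were those at NEURL1B, a ubiquitin ligase gene of the Notch pathway (16.7), ADAMTS12, a secreted metalloprotease gene (16.3), ZNF490 (14.0), which shares the peak with ZNF791, and KCTD16 (13.7), which shares it with YIPF5. The highest knockdown folds were at SLC6A17, G0S2, TUBB2B, THSD1 (9.35) and ACY3 (9.09).

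Inside genes the control library had more peaks and the larger covered length. Peaks covered 13.7 Mb of gene interiors in the control list and 7 Mb in the knockdown list, a ratio of 0.511, against 0.746 at gene ends (15.2 and 11.3 Mb). For covered lengths, the interior was all sequence over 1000 bp inside both ends of a gene of at least 5000 bp. Ends and flanks of other genes were not taken out, so the interior and gene-end lengths can share sequence. Of 7420 genes with a gene-end peak in both lists and a clear interior, 1611 had an interior summit in both, 1110 in the control list only and 280 in the knockdown list only. Flanks, counted in 4665 genes, held a summit in both lists for 510, in the control list only for 547 and in the knockdown list only for 145. Mean peak width was 1063 bp in the control list and 906 bp in the knockdown list.

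The genes that follow were chosen after their values were seen. The largest losses of covered interior were at TIAM2, a Rac activator gene (42682 bp in the control list and 7074 bp in the knockdown list), EXT1, of heparan sulfate synthesis (29613 and 4067 bp), SH3BP4 (29393 and 5125 bp), TENM2 (31594 and 7738 bp) and MYH9, nonmuscle myosin (30886 and 8891 bp). EZR, which encodes ezrin, a linker of membrane and actin (chromosome 6, 158765748 to 158819368), went from 40.8% of its interior covered to 3.27%. The largest gains were at BCL2L1, which encodes the survival factor BCL-XL (chromosome 20, 31664452 to 31723963, 16458 and 25008 bp), LAMB3, a laminin chain (1073 and 7352 bp), DNMBP (1592 and 6933 bp) and HMGA2, a chromatin protein (8905 and 14100 bp). Of 7861 genes with any covered interior, 6600 had less in the knockdown list and 1251 more.

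With equal numbers of strongest peaks the covered interior was 11.6 and 7 Mb, a ratio of 0.603, and single-list genes numbered 604 (control) and 453 (knockdown). The strongest 10000 peaks of each list turned the gene count, to 99 in the control list only and 128 in the knockdown list only, while the covered interior stayed lower in the knockdown list (6.33 and 3.73 Mb).

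**Figure D3:**
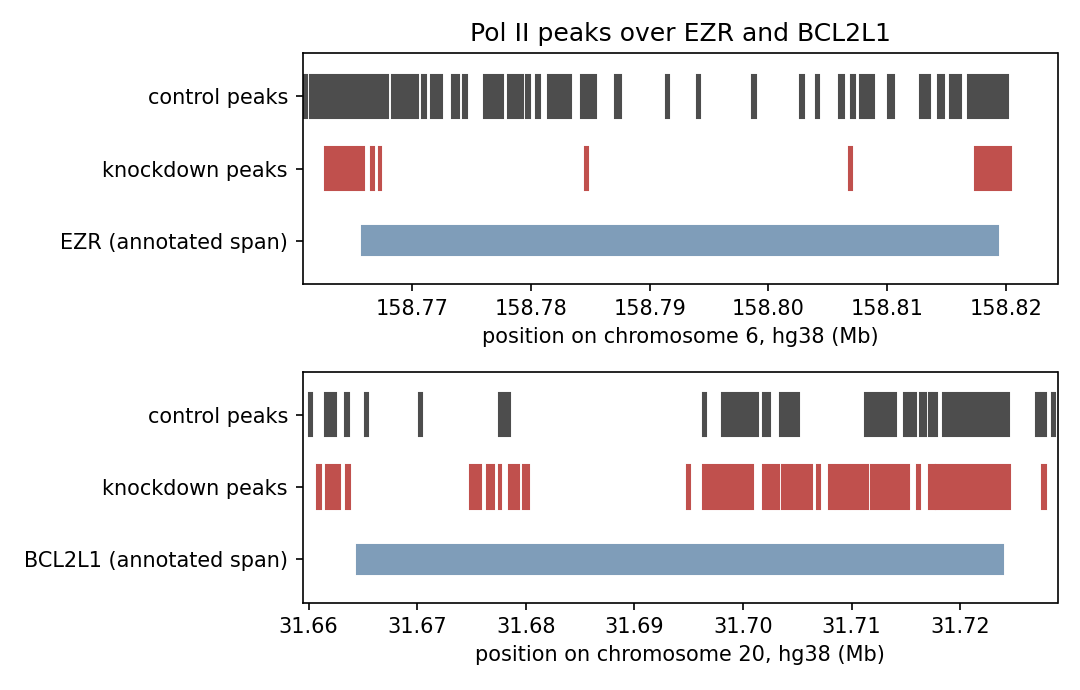
Peaks of the control list (dark) and the knockdown list (red) over EZR on chromosome 6 and BCL2L1 on chromosome 20, with 5000 bp on either side (x axis, hg38 position in Mb); boxes are peaks to scale and the blue bar is the annotated gene. EZR has 27 control and 7 knockdown peaks drawn, and BCL2L1 has 21 and 25.

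**Figure D4:**
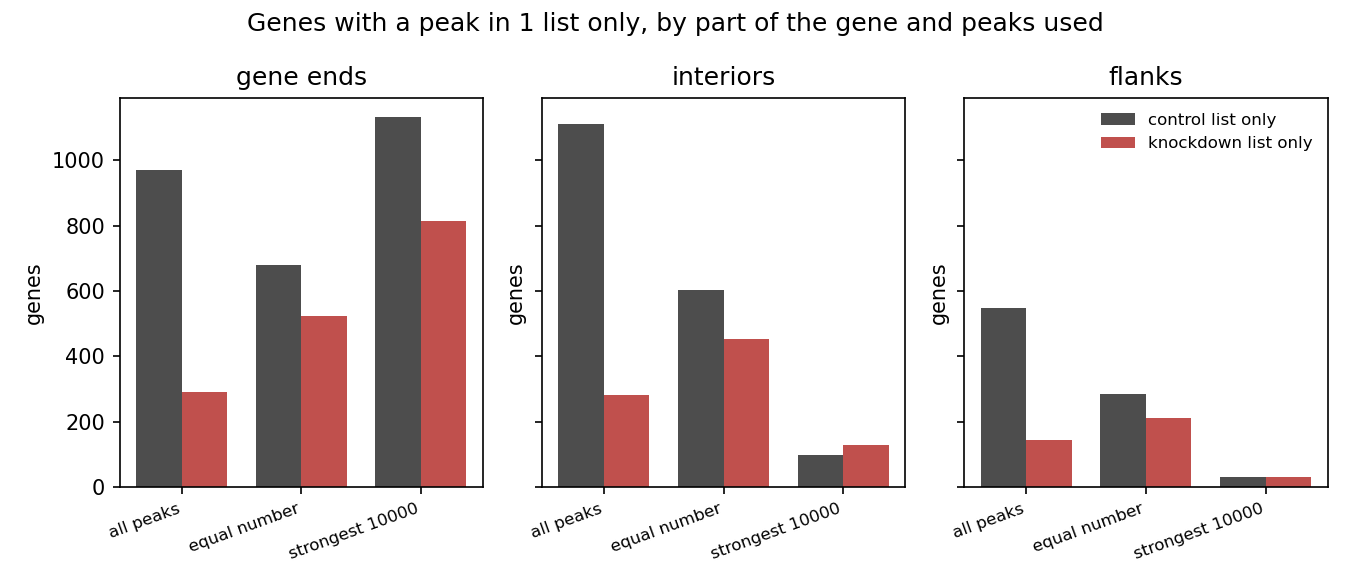
Number of genes (y axis) with a peak in the control list only (dark) or the knockdown list only (red) at gene ends, in interiors and in flanks, using all peaks, equal numbers of strongest peaks or the strongest 10000 (x axis). With all peaks the counts are 970 and 291 at gene ends, 1110 and 280 in interiors, and 547 and 145 in flanks; in interiors the order turns with the strongest 10000 peaks, at 99 and 128.

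Genes of chromosome X kept a gene-end peak less often than genes of other chromosomes. Of 385 X-linked genes with a control gene-end peak, 80.0% (75.7 to 83.7) had one in the knockdown list, where the strength of their control peaks predicted 84.2%. Over all 814 control peaks of chromosome X, 56.6% were overlapped, where strength predicted 56.4%. On the other chromosomes the share ran from 89.2% on chromosome 19 to 94.4% on chromosome 2. By gene length, the share ran from 90.6% to 93.1% over 5 groups of the genes.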

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

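Of the alternatives given here, the control list thinned to the knockdown depth and the stricter gene-end rule were chosen after the data were seen, and the others before the data were examined. The knockdown list was the shorter under each threshold on q and with all sequences, and knockdown peaks were the more often overlapped under each alternative run. More genes had a gene-end peak in the control list only than in the knockdown list only under each alternative run. Interiors and flanks did so too, except with the strongest 10000 peaks. Where a value moved below, the cause was not tested unless stated.

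The share of control peaks overlapped was 55.8% at −log10 q of at least 5. At −log10 q of at least 10 the lists held 18506 control and 13757 knockdown peaks, with 64.4% and 89.8% overlapped. The genes in the control list only then numbered 1630 at gene ends, 491 in interiors and 187 in flanks, and those in the knockdown list only 152 in interiors and 42 in flanks.

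With equal numbers of strongest peaks the overlap was 67.6% and 76.9%, and the gene-end share rose by 1.47 percentage points. The knockdown list alone then had 522 genes at gene ends, interiors had 604 (control only) and 453 (knockdown only), and flanks had 284 (control only). With 10000 peaks in each list, by construction, the overlap was 79.9% and 81.8%. The difference in gene-end share then turned to −1.15 percentage points, with an interval that included 0. Gene-end peaks were in both lists for 7075 genes and in the knockdown list only for 813. Interiors had 99 genes in the control list only and 128 in the knockdown list only, and flanks had 31 and 31.

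Overlap followed its definition. It was 35.6% and 49.0% when at least 0.5 of both peaks had to be shared, 36.6% and 50.4% for summits within 200 bp, and 65.8% and 88.9% for peaks within 1000 bp. The gene-end share rose by 7.09 percentage points with windows of 2000 bp. Any overlap in place of the summit left 172 genes with an interior peak in the knockdown list only, and a flank of 2000 bp gave 221 genes in the knockdown list only. Thinning the control list gave an overlap of 57.1% and 81.3% and a rise in gene-end share of 6.66 percentage points. The stricter gene-end rule left 190 genes in the knockdown list only.

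Of the 588 planned values for the named genes, as the number of lists with a gene-end peak, 84 moved and the rest were the same. Of the 65 planned values for the gene lists 3 left the 95% interval of the reported share, each by reaching 100%: p53 targets with windows of 2000 bp, and DNA replication and interferon-stimulated genes with equal numbers of peaks. These intervals are wide for short lists and held some falls. With windows of 2000 bp the Notch genes fell to 90% (9 of 10, percentile 4.35), the interferon-stimulated genes to 75% (9 of 12) and the neuron markers to 71.4% (5 of 7). A second transcription start per gene, each line of a list counted as a peak, and gene results on all sequences were not run: the gene table holds no transcripts, no 2 peaks of a list had the same start and end, and the table was used for the named chromosomes. No paired analysis was possible because each group held 1 library. The depth limits the weak peaks most, since the lowest peaks rested on 8 reads.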

Other observations

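Of the tests below, only that of peak width against summit height was written before its result was seen. The tests of depth, enrichment, list length and weak interior peaks, and the summit reads and covered interiors of the gene lists, were chosen after the results were seen.

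Matched peaks were narrower after the knockdown. Over 15803 pairs the median width was 1182 bp in the control list and 835 bp in the knockdown list, and 78.9% of the pairs were narrower in the knockdown list. In the 6917 pairs whose scaled knockdown reads reached the control reads, the median width ratio was 0.850 (95% interval 0.839 to 0.858). This does not exclude lower summits as the whole cause. Choosing pairs by noisy reads favours summits that counting error raised in the knockdown list or lowered in the control list. The widths need not share that error. Lower summits, a lower depth at calling and a lower signal beside the summits stay open. So does a narrower spread of Pol II, which NKAP depletion may bring and which was not tested.

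The knockdown list was also the shorter. The control list thinned to the knockdown depth kept 1.27 times the knockdown number (1.27 to 1.28 over 100 random draws). Only summit reads were thinned, and a peak was kept if its summit still passed the threshold. Peaks were not called again, so the number kept can be too high among narrow, weak peaks. Depth alone is therefore not excluded. A lower enrichment in the whole knockdown ChIP stays open: at matched strength the log2 ratio of scaled reads at matched summits differed between gene ends and interiors by −0.012 (95% interval −0.037 to 0.021). Without matching on strength its medians were −0.11 at gene ends, −0.01 in interiors and −0.04 in other genes. Flanks had 0.04 and intergenic sequence 0.03. These medians cover only peaks found in both lists, and 34.3% of control peaks in flanks but 79.8% at gene ends were overlapped. Sites below the knockdown threshold are left out, so the medians do not show whether all kinds of region dropped. A lower level of Pol II on chromatin could also shorten the list, and 1 library per group does not separate it from the yield of an immunoprecipitation.

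Gene interiors lost more peaks than gene ends. List length accounted for much of it: the interior share, knockdown minus control, was −5.47 percentage points with all peaks and −1.60 (−2.34 to −0.847) in lists of equal length. That interval covers counting error only, and neighbouring interior peaks are not independent. Whether the remainder exceeds the variation between libraries cannot be told from 1 library per group. The strongest 10000 peaks of each list gave 0.200 (−0.813 to 1.21), so the difference rests on weaker peaks. Poorer recovery of interior peaks in any pair of libraries stays open: knockdown peaks were found in the control list 11.4 percentage points (10.1 to 12.7) more often at gene ends than in interiors of the same strength. An effect of NKAP on Pol II inside genes may add to this, and it was not tested.

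Summit reads were compared in 10337 genes with summits at the same gene end in both lists, where the median log2 ratio of knockdown to control was −0.12. Cell cycle genes lay lower: the median was −0.45 for the replication-dependent histones (16 genes on 13 peaks, percentile 0.03 among random lists), −0.39 for DNA replication (30 genes, 0.01) and −0.37 for mitosis and G2/M (30 genes, 0.04). Nuclear-encoded oxidative phosphorylation had −0.30 (30 genes, 0.34), and NF-kB targets 0.15 (15 genes, 99.3). Under the rule used first these 5 stood at percentiles 0, 0.03, 0.04, 1.01 and 99.8. The heat shock genes went from 0.97 to 2.85 with the change of rule and glycolysis from 80.7 to 98.5, so that these 2 depended on it. The other 14 lists stood between 5.29 and 81.4. Random lists were matched on strength only. The histone genes compared all lay on chromosome 6 and some shared a peak, so their percentile counts values as separate that are not.

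Single genes, chosen after their values were seen, included CDC6, which loads the replicative helicase, with 71 reads in the control library and 27 in the knockdown library (log2 ratio −1.15, counting interval −1.84 to −0.49), BIRC5, which encodes survivin, with 65 and 22 (−1.31, −2.08 to −0.60), and TOP2A, the mitotic topoisomerase, with 63 and 26 (−1.03, −1.75 to −0.35). CCNB2, a mitotic cyclin gene, went the other way, with 30 and 44 (0.80, 0.10 to 1.52). Among matrix and cytoskeleton genes, COL1A1 had 85 and 22 reads (−1.70, −2.45 to −1.01), TPM1 88 and 23 (−1.69), FN1 62 and 23 (−1.18) and THBS1 137 and 55 (−1.07). VIM, of the same matrix list, went the other way, with 21 and 34 (0.94, 0.12 to 1.80), at a weak peak of its higher-coordinate end. Its strongest peak had its summit in the gene interior in both lists and was outside this comparison. The list as a whole stood at percentile 6.95. Of 3646 genes with at least 50 reads in the control library or, after scaling, in the knockdown library, 35 lay below −1 and 6 above 1. Among the 6, HGS and ARL16 shared a peak, and the control and knockdown peaks compared at INPP5B did not overlap. Nor did those compared at EBF1, among the 35.

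The covered interior moved the same way for some of these groups. Its ratio of knockdown to control was 0.200 for extracellular matrix and osteoblast genes (11 of 12 genes with less, percentile 0.08; 0.264 without THBS1), 0.217 for mitosis and G2/M (21 of 23, 0.03), 0.268 for DNA replication (23 of 24, 0.33) and 0.217 for the unfolded protein and ATF4 response (12 of 13, 1.12). All genes with covered control interiors gave 0.499. Random lists were matched here on the covered control length only. Gene length and peak strength were not matched, so the percentiles can reflect these as well as the group. Oxidative phosphorylation, low in summit reads, was not low here, at 0.623 (5 of 6 with less, 73.6). Ribosomal protein genes kept more, at 0.780 (21 of 26 with less, 99.98), as did immediate early genes, at 0.784 (4 of 13 with less, 99.1; 1.04 without FOSL2). The ratio of 1.00 for NF-kB targets rested on 1 gene, and was 0.599 without BCL2L1. With equal numbers of peaks the matrix, mitosis, replication and ribosomal lists stood at percentiles 0.02, 1.21, 0.46 and 99.8, and the immediate early list at 97.3, inside the central 95%.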
